A study of Mus musculus with 6 samples.

How the data were processed

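RNA was extracted from AGM regions of C57BL/6 mouse embryos at E11.5, and about 1 µg of it went into each library, per the labels' protocols. Libraries were made with a TruSeq RNA kit, which does not mark strand, and sequenced as paired reads of 150 bp on a HiSeq instrument. Per the submitters' processing notes, the authors used TopHat2 2.0.9, HTSeq 0.5.3p9 and the genome build GRCm38, and how the gene models were chosen is not given in the sources used here. The deposited table held RPKM values computed by the authors for 6 libraries, with 1 column per library matched to its sample by a number in the sample's description. The labels speak of littermates without saying which libraries came from the same litter, and the meaning of those numbers is not given. They do not say whether a library came from 1 embryo or several, so p-values measure only the spread between the 2 libraries of a genotype. That spread was pooled over all genotypes, so a p-value of tph2-/- against tph2+/+ also carries the spread of the tph2+/- libraries.

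Of 56826 rows in the table, 33353 carried identifiers of cDNA clones and 27 carried dates in place of gene symbols. Both kinds were left out, which left 23446 rows with gene symbols. Whether clone rows count reads of the gene models again was not measured, and 1186 of 28547 clone rows above 0 held the same 6 values as another row. Clone rows held 30.3% to 30.9% of the summed RPKM of a library. Coordinates and biotypes of named genes came from the GENCODE annotation of GRCm38, and 22056 of the symbols matched the reference table of gene names. The 13 mitochondrially encoded genes had no row under their symbols and were not analysed here.

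The fixed design named a count test first and, for a table of normalized values, limma on the log scale. Because the table held RPKM, the second was used. Genes with a mean of at least 1 RPKM over the 6 libraries were kept (12869 genes), values were taken as log2(RPKM + 1), and limma 3.58.1 in R 4.3.3 was fitted to all 6 libraries in 3 genotype groups with lmFit and eBayes, with the trend and robust options. No covariate entered. A fold change on this scale understates the change of low genes. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and an adjusted p under 0.05 counted as past the threshold. The 3 pairwise comparisons came from the same fit, and a slope on the number of lost alleles gave the trend.

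A total of 45 gene lists had been fixed before the data were examined, and 42 had at least 5 tested genes. The 3 lists not tested were the mitochondrially encoded, germ cell and serotonin receptor lists. Older symbols were matched through synonyms, so that Adgrg1 appears as Gpr56, Cnmd as Lect1 and Spi1 as Sfpi1, and 810 of 825 list entries had a row. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. For each list, the genes past the threshold were also counted after adjustment over the list alone. With a correlation estimated per list, none of the 21, 25 and 10 lists past the threshold in tph2-/- against tph2+/+, tph2+/- against tph2+/+ and tph2-/- against tph2+/- kept its call, and by fry 7, 7 and 2 of all lists passed. The test with an estimated correlation rests on the 3 residual degrees of freedom, so it can drop a list whatever its correlation. In tph2-/- against tph2+/+ the megakaryocyte list had an estimated correlation of -0.000109, under the preset. Its camera adjusted p still went from 3.26e-09 to 0.289. The loss of the megakaryocyte call therefore does not show that correlation between genes produced it. Other lists had estimated correlations far above the preset, such as 0.543 for mesenchyme, 0.491 for erythroid and 0.424 for somite genes. For such lists the camera p-values at the preset may be too small. The test cannot separate their correlation from the few degrees of freedom. Fry tests whether the genes of a list move one way on balance and compares them with no other genes. By fry the progenitor, megakaryocyte, hepatoblast, endoderm and posterior Hox lists passed in both mutant genotypes against tph2+/+. Neural and stress response lists passed in tph2-/- only, and limb bud and cholesterol lists in tph2+/- only. Between the mutant genotypes the neural and limb bud lists passed. The somite, erythroid, smooth muscle and mesenchyme lists passed by fry in no comparison.

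Genes were named by a rule fixed before the data were examined. It took, among genes past the threshold whose groups did not overlap (which chance gives for 33.3% of genes with 2 libraries against 2), the 10 higher and the 10 lower with the largest fold change, leaving out predicted models. Of the latter, 49, 25 and 7 passed in the 3 pairwise comparisons. The rule added a fixed set of serotonin, blood and survival genes, and up to 4 genes in the direction and 2 against the direction of each list past the threshold. A few genes that the rule names are not reported here. Genes of near-identical families, such as globins, histones, metallothioneins and the Serpina1 group, are uncertain because the authors' counting may have split their reads, and antisense genes are uncertain because strand was not marked.

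Read depth was estimated from the deposited RPKM values. Among 2501 low genes, 99.7% had values in whole multiples of a common step in all 6 libraries, within 0.2% of the read number. The lengths of 393 single-transcript genes then gave the reads behind 1 RPKM, with 226 of them within 1% of the mode, and estimated denominators of 38800000 to 46000000 reads. Reads of genes under the filter were computed from those steps as the smallest whole numbers that fit, with exact conditional 95% intervals for ratios from SciPy 1.17.1.

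The gene test was tested on simulated data with the real means and spreads and 200 changed genes. At a log2 change of 0.5 it recovered 86.0% in tph2-/- against tph2+/+, 87.5% in tph2+/- against tph2+/+ and 94.4% in tph2-/- against tph2+/-, and at a change of 1 it recovered 100%, 97.3% and 98.6%. Of the calls, 6.37%, 7.73% and 8.02% were false. The list test recovered 3 of 3 shifted lists in each comparison and called 1, 0 and 2 others. Simulated genes were drawn independently, so these checks do not cover false calls from genes that vary together. In the data the estimated correlation was 0.903 for the hepatoblast list.

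Alternatives were quantile normalization, no filter and a stricter filter on low values, a pseudocount of 0.1, the fit without the robust option, other thresholds, the replicate number as a block, summed Y-linked expression (Ddx3y, Eif2s3y, Kdm5d and Uty) as a covariate, each library left out in turn and a fit of only the 2 groups compared. Tests with the clone rows and without X and Y genes were added after the data had been seen.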

Results

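Gene expression was measured by RNA sequencing in the aorta-gonad-mesonephros (AGM) region of C57BL/6 mouse embryos at E11.5. The AGM is the embryonic tissue around the dorsal aorta in which the first haematopoietic stem cells form, and it also holds mesonephric, gonadal, mesenchymal and neural crest cells. Embryos carried 2, 1 or 0 intact alleles of Tph2, which encodes a tryptophan hydroxylase, the enzyme of the rate-limiting step of serotonin (5-hydroxytryptamine) synthesis. Each genotype (tph2+/+, tph2+/- and tph2-/-) was represented by 2 libraries, 6 in all. The series concerns serotonin made within the AGM and the survival of haematopoietic stem and progenitor cells. The deposited unit was RPKM, reads per kilobase of gene model scaled to the depth of the library. The read totals behind the RPKM values, estimated from the steps between low values, were 46000000 and 44800000 for tph2+/+, 40400000 and 40800000 for tph2+/- and 38800000 and 39200000 for tph2-/-. At an RPKM of 1, a gene model of 2 kb then rested on 77.5 to 92.0 reads per library.

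The targeted gene, Tph2 (chromosome 10, 115078641 to 115185022, minus strand, GRCm38, protein coding), lay close to the detection floor in every library. Its RPKM was 0.0497 and 0.0764 in tph2+/+, 0.0472 and 0.0280 in tph2+/-, and 0.0393 and 0.0680 in tph2-/-. These values correspond to 6 and 9, 5 and 3, and 4 and 7 reads. The tph2-/- to tph2+/+ ratio was 0.854 with a 95% interval of 0.355 to 1.99, which covers counting error only, so Tph2 RNA did not check the genotype labels at this depth. Which part of the gene was disrupted is not given in the sources used here. Tph1, the other tryptophan hydroxylase gene, was also near the floor, with 30 reads over the tph2+/+ libraries, 11 over tph2+/- and 18 over tph2-/-. Its ratio to tph2+/+ was 0.41 (0.185 to 0.842) in tph2+/- and 0.699 (0.367 to 1.3) in tph2-/-. Slc6a4, the serotonin transporter, stayed under the filter at mean RPKM values of 0.404 ± 0.101, 0.690 ± 0.0957 and 0.519 ± 0.117 (SD, n = 2 each, in order of intact alleles). The Slc6a4 ratio was 1.71 (1.32 to 2.21) in tph2+/- and 1.28 (0.969 to 1.69) in tph2-/-. These 95% intervals cover counting error only and not the spread between libraries. Ddc, the next enzyme of serotonin synthesis, had a log2 fold change of -0.29 ± 0.0942 (SE) in tph2-/- against tph2+/+, with a limma adjusted p of 0.0918. Maoa, which breaks serotonin down, had 0.14 ± 0.0819 and an adjusted p of 0.288. Of 10 tested genes of serotonin synthesis, transport and breakdown, 1 rose in tph2-/- and 9 did not pass (1 adjusted over the list alone). The gene was Pcbd1, a pterin recycling enzyme named here after its value was seen (0.56 ± 0.0648, adjusted p = 0.0011), and it also rose in tph2+/- (0.43, adjusted p = 0.00457; 3 genes adjusted over the list alone). The list itself did not pass the camera test in tph2-/- (adjusted p = 0.467) or tph2+/- (0.484) against tph2+/+. Between tph2-/- and tph2+/- its median was -0.0125 while its test leaned up (0.904).

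The 2 tph2+/+ libraries stood apart from the 4 mutant libraries on the first principal component, which held 55.0% of the variance. The second component, with 21.1%, separated tph2+/- from tph2-/-. Replicates correlated across genes at Pearson's r of 0.997 for tph2+/+, 0.993 for tph2+/- and 0.996 for tph2-/-, where genes are not independent replicates. Sex was not balanced over the genotypes. Xist, the RNA that coats the inactive X chromosome of females, stood at 79.2 and 76.3 RPKM in tph2+/+ and 101 in tph2+/- replicate 1, against 0.0916 in tph2+/- replicate 2 and 0.0590 and 0.114 in tph2-/-. Y-linked Ddx3y was at most 0.0214 RPKM in the 3 libraries with Xist and 8.69, 9.82 and 8.14 in the others. Both tph2+/+ libraries thus carried a female pattern and both tph2-/- libraries a male one, so genotype and sex coincided in that comparison.

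**Figure D1:**
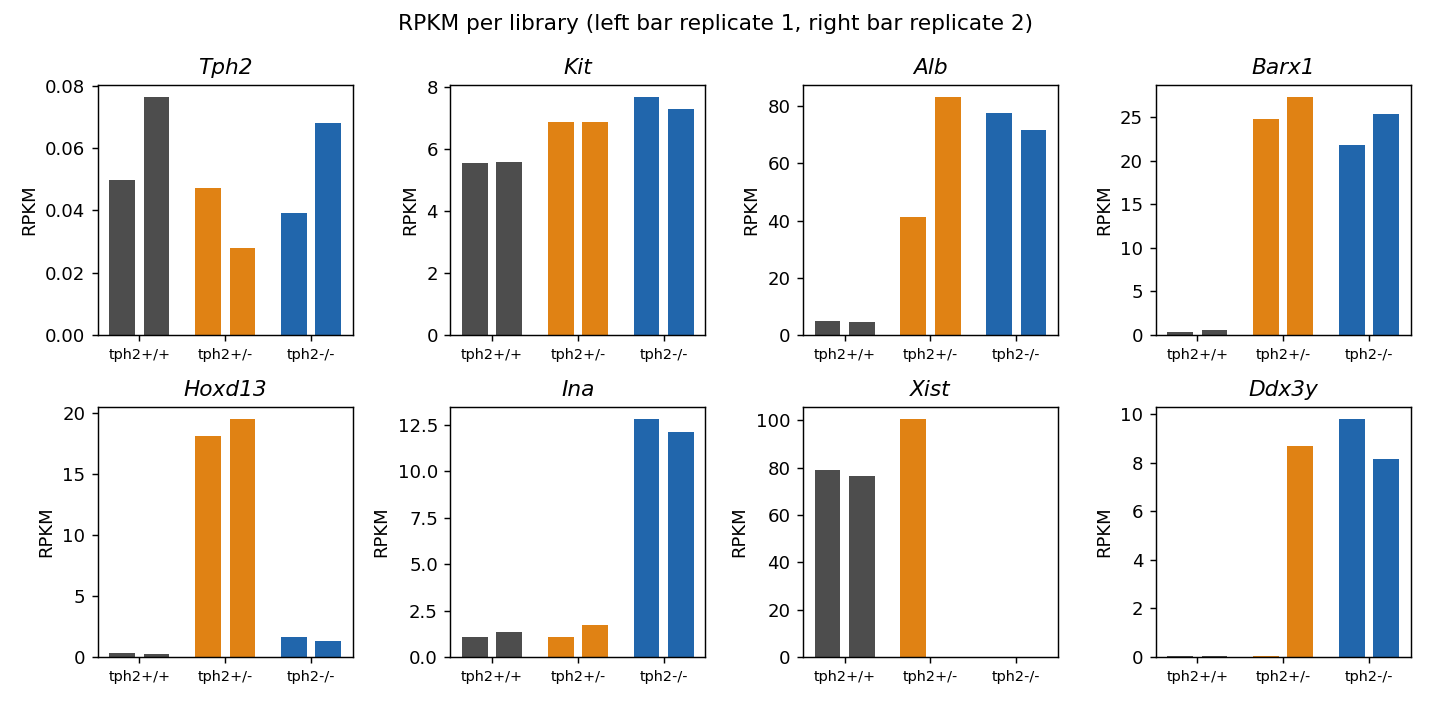
RPKM of 8 genes in each of the 6 libraries, with 1 bar per library, grouped by tph2 genotype, on linear axes that start at 0 and differ between panels. Tph2 stayed under 0.08 in all libraries, Alb and Barx1 were higher in the 4 mutant libraries than in tph2+/+, Hoxd13 was high in tph2+/-, Ina was high in tph2-/-, and Xist and Ddx3y split the tph2+/- pair.

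The comparison of tph2-/- with tph2+/+ asks what the loss of both alleles changed in this tissue. In no comparison was genotype told apart from differences in the tissue dissected. All 17 tested hepatoblast genes rose in tph2-/-, with a median log2 fold change of 2.59, as did all 8 neural tube and neuron genes, 9 of 13 megakaryocyte, 13 of 23 progenitor and 9 of 21 erythroid genes, while 9 of 19 somite and skeletal muscle, 7 of 12 smooth muscle and 7 of 22 mesenchyme genes fell. No list kept its call with an estimated correlation between genes, where the test rests on 3 residual degrees of freedom and the smallest adjusted p was 0.289. Alb, the gene for serum albumin, went from 4.68 ± 0.176 RPKM (SD, n = 2) in tph2+/+ to 74.5 ± 4.08 in tph2-/- (log2 fold change 3.73 ± 0.372 SE, adjusted p = 0.0187). Barx1, a transcription factor of stomach mesenchyme (chromosome 13, 48662998 to 48666507, plus strand), went from 0.463 ± 0.18 to 23.6 ± 2.53 RPKM (4.07 ± 0.102, adjusted p = 3.03e-07). In all, 1241 of 12869 tested genes passed an adjusted p of 0.05 by limma, 751 higher and 490 lower in tph2-/-, and 116 of them by at least 2-fold. After quantile normalization the split was 548 higher and 667 lower. With Y-linked expression as a term in the fit, 422 genes passed, and 285 of the 1241 remained. The count was 466 and 383 without tph2+/+ replicate 1 or 2, 388 and 809 without tph2-/- replicate 1 or 2, and 1530 and 1517 without tph2+/- replicate 1 or 2.

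The hepatoblast list led the higher side of this comparison, with 17 of 17 genes higher, also when adjusted over the list alone (camera adjusted p = 3.13e-26; adjusted p = 0.361 with an estimated correlation). Apoa1 rose by 3.32 ± 0.131, Afp by 3.17 ± 0.228, Rbp4 by 2.76 ± 0.158 and Ttr by 2.62 ± 0.0827 on the log2 scale. Other liver-secreted proteins among the largest changes were Serpina6 at 3.19 ± 0.295, Ambp at 3.12 ± 0.13 and Serpina1b at 2.99 ± 0.112, the last from a family of near-identical genes whose reads may be split. Genes of gut and foregut endoderm rose as well, 6 of 9 (7 adjusted over the list alone, with 1 lower), with a median of 0.38 (adjusted p = 0.000583; adjusted p = 0.361 with an estimated correlation). Foxa2 rose by 1.08 ± 0.114, Foxa1 by 0.93 ± 0.122 and Shh by 0.88 ± 0.102. Pdx1, a pancreas and duodenum transcription factor under the filter, had 0 reads in both tph2+/+ libraries, 36 and 23 in tph2+/- and 39 and 27 in tph2-/-.

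All 8 tested genes of the neural tube and neuron list rose in tph2-/- (8 adjusted over the list alone), with a median of 1.20 (camera adjusted p = 2.19e-11; adjusted p = 0.361 with an estimated correlation). The full list held 19 genes, and the others lay under the filter on mean RPKM. A gene can pass that filter through the group where it is high. Sox2, a neural progenitor factor, rose by 1.70 ± 0.0814, Elavl3 by 1.44 ± 0.111, Dcx by 1.26 ± 0.0891 and Map2 by 1.14 ± 0.0776. The posterior Hox list rose too, with 7 of 13 genes higher (8 higher and 1 lower adjusted over the list alone) and a median of 0.62 (adjusted p = 3.24e-06; adjusted p = 0.361 with an estimated correlation). Hoxc11 rose by 2.85 ± 0.16, Hoxd11 by 1.45 ± 0.0855, Hoxa11 by 1.35 ± 0.0889 and Hoxd10 by 1.25 ± 0.0888. Hoxa11 overlaps an annotated antisense gene, and the library kit does not mark strand, so reads of the pair cannot be told apart.

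Genes of haematopoietic stem and progenitor cells rose in 13 of 23 cases (13 higher and 1 lower adjusted over the list alone), with a median of 0.41 (camera adjusted p = 5.36e-06; adjusted p = 0.361 with an estimated correlation). Spn rose by 1.18 ± 0.12, Gfi1b by 1.13 ± 0.108, Gpr56 by 0.91 ± 0.0705 and Lmo2 by 0.85 ± 0.084. Kit, the stem cell factor receptor, rose from 5.55 ± 0.0172 to 7.47 ± 0.273 RPKM (0.37 ± 0.0638, adjusted p = 0.00806). Runx1, the factor required for blood formation from aortic endothelium, had 1.20 ± 0.0783 RPKM in tph2+/+ and 1.33 ± 0.0949 in tph2-/- (0.08 ± 0.125, adjusted p = 0.703). Gfi1, another factor of that transition, had 32 reads in tph2+/+ and 27 in tph2-/-, a ratio of 0.983 with a counting interval of 0.566 to 1.69. Of 13 megakaryocyte and platelet genes 9 rose (10 adjusted over the list alone), with a median of 0.60 (adjusted p = 3.26e-09; adjusted p = 0.289 with an estimated correlation), among them Ppbp at 1.16 ± 0.0835, Plek at 1.10 ± 0.0978 and Pf4 at 1.01 ± 0.0599. Of 21 erythroid genes 9 rose (10 adjusted over the list alone), with a median of 0.48 (adjusted p = 1.12e-08; adjusted p = 0.378 with an estimated correlation). Gata1 rose by 1.15 ± 0.0886 and Klf1 by 1.14 ± 0.11, while Hbb-bt, a globin gene with close paralogs, had -0.26 ± 0.694 (adjusted p = 0.847). The macrophage list rose with 2 of 13 genes higher (8 adjusted over the list alone) and a median of 0.31 (adjusted p = 0.00297; adjusted p = 0.41 with an estimated correlation); these were Tyrobp at 0.55 ± 0.103 and C1qc at 0.37 ± 0.0967. With Y-linked expression in the fit, the erythroid median was 0.195 (adjusted p = 0.203) and the macrophage median 0.108 (adjusted p = 0.568). The hepatoblast genes were higher in the same libraries.

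**Figure D2:**
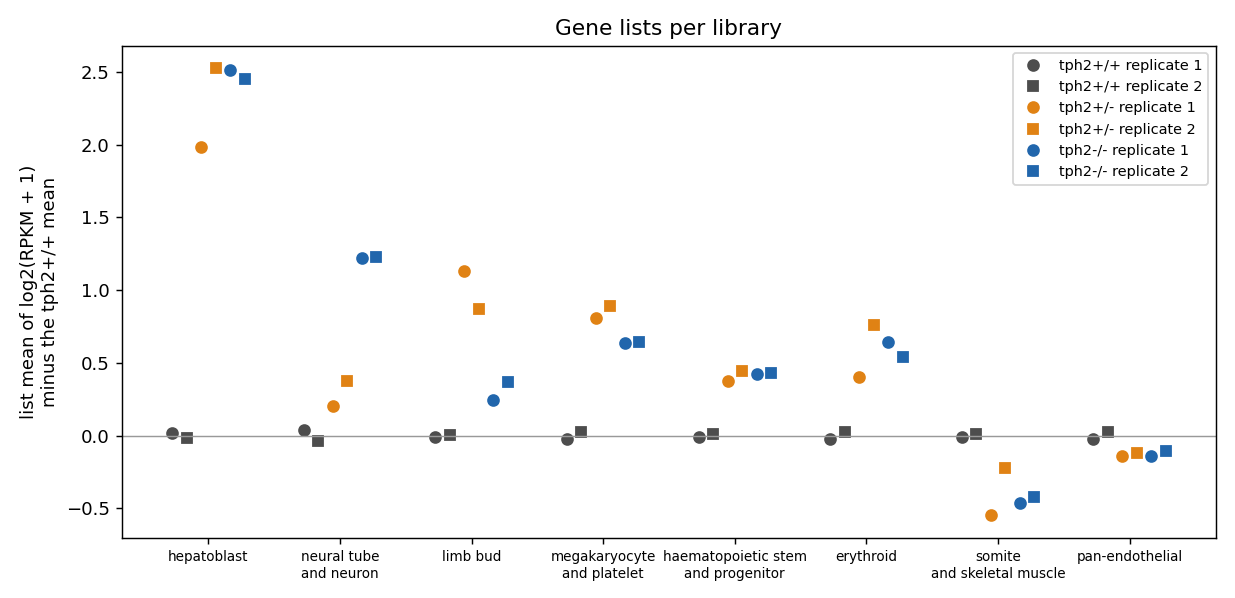
Mean log2(RPKM + 1) of 8 gene lists in each library, minus the mean of the 2 tph2+/+ libraries; circles are replicate 1 and squares replicate 2, and colour marks genotype. Hepatoblast genes lay above tph2+/+ in all 4 mutant libraries and lower in tph2+/- replicate 1 than in the other 3, neural genes were highest in tph2-/-, and limb bud genes were highest in tph2+/-.

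On the lower side, 9 of 19 somite and skeletal muscle genes fell (13 adjusted over the list alone), with a median of -0.48 (camera adjusted p = 1.19e-10; adjusted p = 0.361 with an estimated correlation). Tnnc2 fell by 0.63 ± 0.0672, the myogenic factors Myf5 by 0.59 ± 0.113 and Myod1 by 0.52 ± 0.109, and the muscle actin Acta1 by 0.55 ± 0.0937. Mesenchyme and extracellular matrix genes fell in 7 of 22 cases (14 adjusted over the list alone), with a median of -0.29 (adjusted p = 8.54e-09; adjusted p = 0.378 with an estimated correlation), including Tnc at -0.64 ± 0.111 and Fn1, fibronectin, at -0.44 ± 0.0672. Smooth muscle and pericyte genes fell in 7 of 12 cases (8 lower and 2 higher adjusted over the list alone), with a median of -0.30 (adjusted p = 0.000155; adjusted p = 0.41 with an estimated correlation). Acta2 fell by 0.63 ± 0.0988, Tagln by 0.47 ± 0.0501 and Pdgfrb by 0.40 ± 0.055. Of 12 gonad and coelomic epithelium genes 4 fell (6 lower and 1 higher adjusted over the list alone), namely Nr5a1, Wt1, Cbx2 and Emx2, with a list median of -0.19 (adjusted p = 0.00551; adjusted p = 0.361 with an estimated correlation). Single genes with large falls were Tbx5, a forelimb and heart factor, at -1.18 ± 0.0956, Thbs4 at -0.91 ± 0.0763, Tbx3 at -0.74 ± 0.0638, Amhr2 at -0.73 ± 0.0959 and Dbh, the enzyme that makes noradrenaline, at -0.78 ± 0.0689. The sympathoadrenal and neural crest list, which holds Dbh, had 9 genes higher and 6 lower of 19 (11 and 6 adjusted over the list alone). It did not pass (median 0.223, camera adjusted p = 0.135).

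No pan-endothelial gene of 18 passed singly, also when adjusted over the list alone, and the list fell as a set with a median of -0.12 (camera adjusted p = 0.000334; adjusted p = 0.361 with an estimated correlation). Cdh5, the endothelial cadherin, had 29.2 ± 0.696 RPKM in tph2+/+ and 26.5 ± 0.48 in tph2-/- (-0.13 ± 0.0529, adjusted p = 0.146). Of 14 arterial endothelium genes 4 fell and 1 rose (5 and 2 adjusted over the list alone), with a median of -0.18 (adjusted p = 0.00374; adjusted p = 0.378 with an estimated correlation). Unc5b fell by 0.51 ± 0.0682, Gja5 by 0.41 ± 0.0898, and the Notch target and ligand genes Hey1 and Jag1 each by 0.38, while Cxcr4 rose by 0.42 ± 0.093. Wnt targets fell with 5 of 13 genes lower (6 adjusted over the list alone), Lef1, Nkd2, Apcdd1, Notum at -0.52 ± 0.113 and Axin2 at -0.30 ± 0.0726, and a median of -0.13 (adjusted p = 0.00551; adjusted p = 0.378 with an estimated correlation). In the BMP and TGF-beta target list, Bmp4 and Bambi fell and Id2 and Id4 rose (5 lower and 2 higher adjusted over the list alone), with a median of -0.14 (adjusted p = 0.0076; adjusted p = 0.361 with an estimated correlation). With Y-linked expression in the fit, the Wnt list (median -0.10, adjusted p = 0.168) and the BMP and TGF-beta list (median -0.0197, adjusted p = 0.203) no longer passed.

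Cytosolic ribosomal protein genes rose as a set with a median of 0.098, though 1 of 49 passed singly, Rplp1 (0 adjusted over the list alone; camera adjusted p = 0.00012; adjusted p = 0.54 with an estimated correlation), and after quantile normalization that median was 0.0342 (adjusted p = 0.0575). Nuclear-encoded oxidative phosphorylation genes rose with Sdhd, Uqcrq and Uqcr11 higher of 35 (3 adjusted over the list alone) and a median of 0.113 (adjusted p = 0.000155; adjusted p = 0.431 with an estimated correlation). Hypoxia and glycolysis genes rose with 6 of 22 higher (7 adjusted over the list alone) and a median of 0.133 (adjusted p = 0.00104; adjusted p = 0.361 with an estimated correlation), including Ndrg1 at 0.50 ± 0.0965 and Ldha at 0.35 ± 0.0498. The integrated stress response list rose with 2 of 18 higher (4 adjusted over the list alone), Asns and Psat1, enzymes of amino acid synthesis, at 0.58 ± 0.0664 and 0.50 ± 0.0502 (list median 0.13; adjusted p = 0.0148; adjusted p = 0.378 with an estimated correlation). Without tph2-/- replicate 2 its median was 0.0882 (adjusted p = 0.0966). The cholesterol synthesis list fell with a median of -0.0899 and 1 gene lower and 1 higher of 22 (1 and 1 adjusted over the list alone; adjusted p = 0.00311; adjusted p = 0.361 with an estimated correlation). With Y-linked expression in the fit, the hypoxia (median 0.0919, adjusted p = 0.288), stress response (median 0.101, adjusted p = 0.202) and cholesterol (median -0.0748, adjusted p = 0.0748) lists did not pass.

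Cell survival genes, which the series title concerns, gave few calls. RNA came from the whole AGM region, so changes within its haematopoietic cells alone were not resolved. Of 26 pro-apoptotic genes 3 rose in tph2-/- and none fell (3 adjusted over the list alone), and the list did not pass, with a median of 0.00921 and a test that leaned down (camera adjusted p = 0.848). Bbc3, a BH3-only death gene, rose from 2.98 ± 0.0765 to 3.95 ± 0.159 RPKM (0.31 ± 0.0763, adjusted p = 0.0362). Bid, named after its value was seen, rose as well (0.46 ± 0.0783, adjusted p = 0.00748). Cdkn1a, a cell cycle inhibitor, fell from 20.4 ± 0.216 to 15.7 ± 0.807 RPKM (-0.36 ± 0.0708, adjusted p = 0.015). Foxo1 had -0.08 ± 0.0861 (adjusted p = 0.557) and Bcl2l11, another BH3-only gene, -0.04 ± 0.0643 (adjusted p = 0.753). Fasl was listed at 0 in both tph2+/+ libraries, at 0 and 0.0253 RPKM in tph2+/- and at 0.0133 and 0 in tph2-/-. FoxO targets had Bbc3, Sod2, Igfbp1 and Bnip3 higher and Cdkn1a lower of 23, of which Sod2 and Igfbp1 were named after their values were seen (5 and 1 adjusted over the list alone, camera adjusted p = 0.245). The p53 targets (adjusted p = 0.848), the PI3K-AKT signalling genes (0.605), the anti-apoptotic genes (0.814) and the cell cycle genes (0.135) did not pass either. After quantile normalization the cell cycle list passed (median 0.0572, adjusted p = 0.033).

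The comparison of tph2+/- with tph2+/+ asks what the loss of 1 allele changed. Here too all 17 hepatoblast genes rose, with 11 of 13 megakaryocyte, 8 of 21 erythroid and 11 of 23 progenitor genes (1 progenitor gene, Meis1, fell), and 7 of 13 posterior Hox genes rose while Hoxb9 and Hoxc9 fell. No list kept its call with an estimated correlation between genes, where the test rests on 3 residual degrees of freedom and the smallest adjusted p was 0.128. Barx1 stood at 26.0 ± 1.78 RPKM (SD, n = 2) against 0.463 ± 0.18 (log2 fold change 4.21 ± 0.102 SE, adjusted p = 1.12e-07). Hoxd13, a factor of distal limb and genital tubercle (chromosome 2, 74668310 to 74671599, plus strand), stood at 18.8 ± 1.02 RPKM against 0.261 ± 0.0393 (3.97 ± 0.0929, adjusted p = 1.12e-07). In all, 782 of 12869 genes passed by limma, 531 higher and 251 lower, 105 of them by at least 2-fold. After quantile normalization the split was 408 higher and 370 lower. Without tph2+/+ replicate 1 or 2 the count was 325 or 339. Without the male tph2+/- replicate 2, which leaves 1 female tph2+/- library against 2 female tph2+/+ libraries, 662 genes passed, and 491 of the 782 remained.

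All 17 hepatoblast genes rose in tph2+/- (17 adjusted over the list alone), with a median of 2.28 (camera adjusted p = 1.46e-30; adjusted p = 0.333 with an estimated correlation). Alb was at 41.3 RPKM in replicate 1 and 83.2 in replicate 2, Apoa1 rose by 3.15 ± 0.131 and Hnf4a, a liver transcription factor, by 1.40 ± 0.121. Megakaryocyte and platelet genes rose in 11 of 13 cases (13 adjusted over the list alone), with a median of 0.91 (adjusted p = 1.49e-15; adjusted p = 0.128 with an estimated correlation), led by Ppbp at 1.47 ± 0.0835 and Pf4 at 1.30 ± 0.0599. Erythroid genes rose in 8 of 21 cases (11 adjusted over the list alone), with a median of 0.48 (adjusted p = 5.86e-10; adjusted p = 0.422 with an estimated correlation), with Gata1 at 1.21 ± 0.0886. Of 23 haematopoietic stem and progenitor genes 11 rose and Meis1 fell (13 and 2 adjusted over the list alone), with a median of 0.26 (adjusted p = 8.02e-06; adjusted p = 0.333 with an estimated correlation). Itga2b rose by 0.99 ± 0.0748, Lmo2 by 0.86 ± 0.084 and Kit by 0.26 ± 0.0638 (adjusted p = 0.045), and Runx1 had 0.21 ± 0.125 (adjusted p = 0.417). Gut and foregut endoderm genes rose in 5 of 9 cases (8 adjusted over the list alone), with a median of 0.48 (adjusted p = 3.48e-06; adjusted p = 0.333 with an estimated correlation). Macrophage genes had a median of 0.19 with none past singly, also when adjusted over the list alone (adjusted p = 0.0325; adjusted p = 0.49 with an estimated correlation). That median was 0.12 without tph2+/- replicate 2 (adjusted p = 0.336), 0.208 without tph2+/+ replicate 2 (0.0504) and 0.114 with Y-linked expression in the fit (0.356).

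Limb bud genes rose in 6 of 11 cases and Meis2 fell (7 and 1 adjusted over the list alone), with a median of 0.71 (camera adjusted p = 3.48e-06; adjusted p = 0.333 with an estimated correlation). Beside Hoxd13, Hoxa13 rose by 2.12 ± 0.102, Lmx1b, a factor of the dorsal limb, by 1.30 ± 0.128 and Hand2 by 0.60 ± 0.0599. Of 13 posterior Hox genes 7 rose and 2 fell (7 and 2 adjusted over the list alone), with a median of 0.95 (adjusted p = 1.4e-05; adjusted p = 0.422 with an estimated correlation). Hoxd12 rose by 2.54 ± 0.108 and Hoxa11 by 2.52 ± 0.0889, with the antisense gene Hoxa11as at 3.17 ± 0.0892, whereas Hoxb9 fell by 0.86 ± 0.0812 and Hoxc9 by 0.79 ± 0.0887. The anterior Hox list fell with 4 of 13 genes lower (4 lower and 3 higher adjusted over the list alone), Hoxd4 at -0.58 ± 0.0609 and Hoxc4 at -0.54 ± 0.0541 among them, with a median of -0.0286 (adjusted p = 0.0191; adjusted p = 0.478 with an estimated correlation). Without tph2+/- replicate 1 that median was 0.0135 (adjusted p = 0.117). Cartilage genes rose in 6 and fell in 2 of 13 cases (8 and 2 adjusted over the list alone), with Lect1 at 1.03 ± 0.107 and Pax1 at -0.60 ± 0.119 (list median 0.315; adjusted p = 0.0205; adjusted p = 0.478 with an estimated correlation). That median was 0.308 without tph2+/- replicate 2 (adjusted p = 0.0802) and 0.31 with Y-linked expression in the fit (adjusted p = 0.0794). Neural tube genes rose in 4 of 8 cases, Sox2, Map2, Dcx and Nkx6-1 (4 higher and 2 lower adjusted over the list alone; median 0.432; adjusted p = 0.0365; adjusted p = 0.49 with an estimated correlation), with Sox2 at 0.54 ± 0.0814. The neural median was 0.276 without tph2+/- replicate 2 (adjusted p = 0.27), 0.385 without tph2+/+ replicate 2 (0.0933), 0.432 without tph2-/- replicate 1 or 2 (0.0563 and 0.0561), 0.0471 with no filter (0.12) and 0.274 with Y-linked expression in the fit (0.272).

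Somite and skeletal muscle genes fell in 5 of 19 cases in tph2+/- (13 adjusted over the list alone), with a median of -0.44 (camera adjusted p = 3.31e-11; adjusted p = 0.376 with an estimated correlation), including Pax3 at -0.67 ± 0.121 and Myf5 at -0.62 ± 0.113. Wt1, a factor of coelomic epithelium and kidney, fell by 0.73 ± 0.0649, Gata3 by 0.63 ± 0.0924 and Emx2 by 0.52 ± 0.0759. These stood in the mesonephros list, with 7 genes lower and 3 higher of 15 and a median of -0.299 (8 and 4 adjusted over the list alone; adjusted p = 0.0286; adjusted p = 0.478 with an estimated correlation). The gonad list had Nr5a1, Wt1 and Emx2 lower and Lhx9 and Sox9 higher of 12 (6 and 2 adjusted over the list alone; adjusted p = 0.0286; adjusted p = 0.422 with an estimated correlation). Without tph2+/+ replicate 2 the median was -0.196 for the mesonephros list (adjusted p = 0.0698) and -0.144 for the gonad list (0.0661), and without tph2+/- replicate 1 it was -0.0817 for the gonad list (0.127). The mesonephros median was -0.303 both without tph2+/- replicate 2 (0.0802) and with Y-linked expression in the fit (0.0846), and -0.395 after quantile normalization (0.0562), so this list lost its call in these 3 settings at a median as large as reported. Arterial genes fell with Gja5, Hey1 and Hey2 lower of 14 (4 adjusted over the list alone), at a median of -0.19 (adjusted p = 1.32e-05; adjusted p = 0.376 with an estimated correlation). Pan-endothelial genes fell at a median of -0.11 with Ramp2 lower of 18 (6 adjusted over the list alone; adjusted p = 5.79e-05; adjusted p = 0.376 with an estimated correlation). Among single genes, Mid1, an X-linked gene at the pseudoautosomal boundary (chromosome X, 169685199 to 170005736, plus strand), was at 23.3 ± 0.622 RPKM in tph2+/+, 6.66 ± 0.458 in tph2+/- and 18.1 ± 0.462 in tph2-/-. It fell in tph2+/- against tph2+/+ (-1.67 ± 0.0636, adjusted p = 1.8e-06). Meox1, a somite factor, fell by 0.87 ± 0.0538, Dbh by 0.83 ± 0.0689 and Hoxc8 by 0.82 ± 0.0656.

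Further lists passed in tph2+/-, and none kept its call with an estimated correlation. Cholesterol synthesis genes had a median of -0.125, with 3 genes lower, Hmgcs1 and Sqle among them, and 1 higher of 22 (9 and 1 adjusted over the list alone; camera adjusted p = 7.11e-06; adjusted p = 0.277 with an estimated correlation). Notch genes had -0.136, with the targets Hey1, Hey2 and Heyl lower of 20 (5 lower and 1 higher adjusted over the list alone; adjusted p = 0.000132; adjusted p = 0.422 with an estimated correlation). Smooth muscle genes had -0.16, with Tagln lower of 12 (5 lower and 1 higher adjusted over the list alone; adjusted p = 0.00028; adjusted p = 0.478 with an estimated correlation). Histone genes had -0.21, with Hist1h2bj and Hist1h3c lower of 12 (2 adjusted over the list alone; adjusted p = 0.0191; adjusted p = 0.456 with an estimated correlation). Mesenchyme genes had -0.135, with Fn1 lower and Prrx1 higher of 22 (2 and 1 adjusted over the list alone; adjusted p = 0.00854; adjusted p = 0.599 with an estimated correlation). Ribosomal protein genes had 0.0948, with Rplp1 higher of 49 (0 adjusted over the list alone; adjusted p = 2.23e-05; adjusted p = 0.49 with an estimated correlation). Oxidative phosphorylation genes had 0.0906, with none of 35 past singly, also when adjusted over the list alone (adjusted p = 0.000754; adjusted p = 0.49 with an estimated correlation). Hypoxia and glycolysis genes had 0.109, with Slc2a3, Ldha, Bnip3 and Tpi1 higher of 22 (8 adjusted over the list alone; adjusted p = 0.00546; adjusted p = 0.422 with an estimated correlation). Integrated stress response genes had 0.133, with Trib3, Asns and Psat1 higher of 18 (4 higher and 1 lower adjusted over the list alone; adjusted p = 0.0433; adjusted p = 0.478 with an estimated correlation). Without tph2+/- replicate 1 the mesenchyme median was -0.0032 (adjusted p = 0.781), and smooth muscle (-0.141, 0.0554), stress response (0.131, 0.0554), histone (-0.152, 0.0937) and oxidative phosphorylation genes (0.0677, 0.117) did not pass either, each given with its median and adjusted p. Without tph2+/+ replicate 2 the lists lost were ribosomal protein genes (0.064, 0.0658), oxidative phosphorylation (0.0632, 0.0804), the stress response (0.115, 0.147) and mesenchyme (-0.107, 0.0504). Without tph2+/+ replicate 1 histones were lost (-0.214, 0.0585), and without tph2+/- replicate 2 hypoxia (0.0911, 0.146) and the stress response (0.107, 0.114). After quantile normalization mesenchyme had -0.15 (0.0927). With Y-linked expression in the fit the hypoxia (0.0917, 0.155) and stress response (0.107, 0.108) lists did not pass. Pro-apoptotic genes did not pass as a list (adjusted p = 0.34), with 2 of 26 genes higher (3 adjusted over the list alone). Both were named after their values were seen. They were Bid (0.42 ± 0.0783, adjusted p = 0.015) and Pmaip1, a BH3-only death gene at 5.34 and 2.30 RPKM in tph2+/- and 0.295 and 0.269 in tph2+/+ (1.83 ± 0.299, adjusted p = 0.026). Bbc3 had 0.26 ± 0.0763 (adjusted p = 0.0886).

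Both mutant genotypes were set against the same 2 tph2+/+ libraries, and their calls overlapped. In both comparisons 376 genes were higher, where independent lists of 751 and 531 would share 31.0, and 137 were lower, where 9.56 would be shared. Unchanged groups simulated against shared controls gave a mean of 0.56 and at most 4 such genes over 50 draws. Genes were drawn independently there, so the range over draws may be too narrow for genes that vary together. Libraries were drawn with the spread within a genotype. A difference that both tph2+/+ libraries share for a reason other than genotype was therefore not simulated, and the draws cannot exclude it. The log2 fold changes of the 2 comparisons correlated across genes at a Pearson's r of 0.76, against a simulated mean of 0.503 and a highest draw of 0.594. Their covariance was 0.0493, against a mean of 0.00536 in the simulation. The controls were not split, which would leave 1 tph2+/+ library for each comparison, so part of the excess may come from sharing them.

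**Figure D3:**
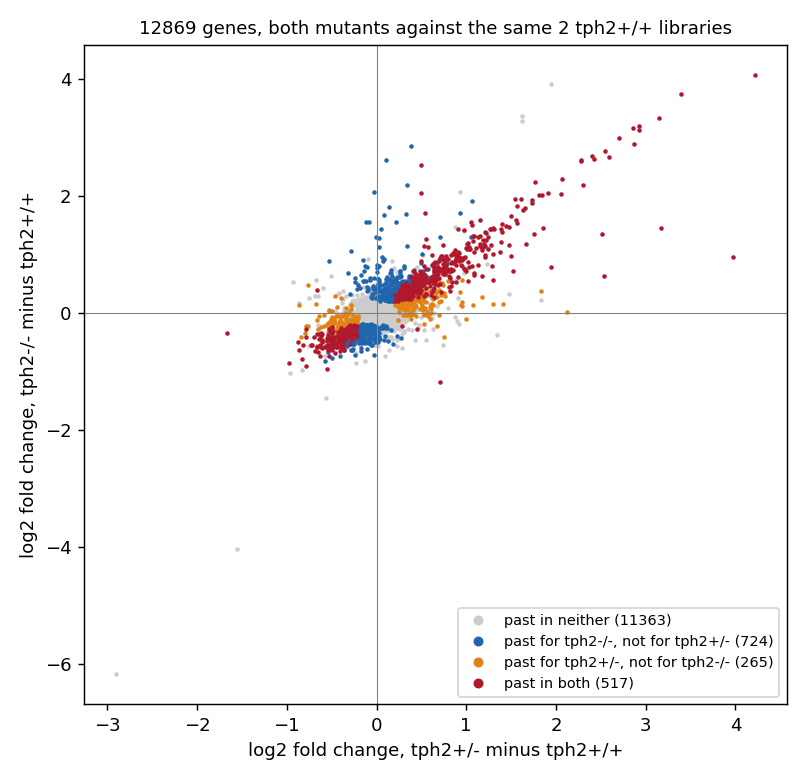
Log2 fold change of tph2-/- (vertical axis) and of tph2+/- (horizontal axis) against the same tph2+/+ libraries, 1 point per gene for 12869 genes, coloured by which comparison passed an adjusted p of 0.05. Of the genes, 517 passed in both, 724 in the tph2-/- comparison and not the other, and 265 in the tph2+/- comparison and not the other.

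The comparison of tph2-/- with tph2+/- asks what the loss of the second allele changed. The difference is taken between mutant libraries, while the spread comes from all 6 libraries. Ina, a neuronal intermediate filament (chromosome 19, 47014698 to 47025327, plus strand), stood at 12.5 ± 0.523 RPKM (SD, n = 2) in tph2-/- and 1.39 ± 0.459 in tph2+/- (log2 fold change 2.51 ± 0.129 SE, adjusted p = 2.56e-05). Hoxd13 stood at 1.46 ± 0.217 RPKM against 18.8 ± 1.02 (-3.01 ± 0.0929, adjusted p = 1.6e-06). Of 12869 genes 166 passed by limma, 96 higher and 70 lower in tph2-/-, and 34 by at least 2-fold. With only the 2 groups compared in the fit 130 passed, and without either tph2+/+ library 129. Without tph2-/- replicate 1 or 2 the count was 57 or 74. Without the female tph2+/- replicate 1, which leaves male libraries on both sides, 288 genes passed, 110 higher and 178 lower, and 132 of the 166 remained.

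Of 8 neural tube and neuron genes 7 rose from tph2+/- to tph2-/- (7 adjusted over the list alone), with a median of 0.90 (camera adjusted p = 3.37e-14; adjusted p = 0.396 with an estimated correlation). Fabp7, a marker of radial glia, rose by 1.85 ± 0.162, Elavl3 by 1.39 ± 0.111, Sox2 by 1.16 ± 0.0814 and Nefl by 0.99 ± 0.0809. The Notch target Hes5 rose by 2.09 ± 0.113, Nhlh1 by 1.66 ± 0.115, Calb2 by 1.64 ± 0.125, Sst by 1.58 ± 0.117 and Zic1 by 1.42 ± 0.148. In the sympathoadrenal and neural crest list 5 of 19 genes rose and Hand2 fell (8 and 1 adjusted over the list alone; median 0.19; adjusted p = 2.37e-05; adjusted p = 0.57 with an estimated correlation). The genes that rose were Tubb3 at 1.66 ± 0.106, Stmn2 at 1.34 ± 0.109, Elavl4 at 0.92 ± 0.109, Insm1 at 0.69 ± 0.101 and Isl1 at 0.55 ± 0.0733, and the chromaffin gene Chga had -0.12 ± 0.0891 (adjusted p = 0.577). Hoxc11 was also higher, by 2.47 ± 0.16.

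Limb bud genes were lower in 5 and higher in 1 of 11 cases (6 and 1 adjusted over the list alone), with a median of -0.26 (camera adjusted p = 7.97e-06; adjusted p = 0.422 with an estimated correlation). Hoxa13 fell by 2.11 ± 0.102, Tbx5 fell by 1.89 ± 0.0956 and Hand2 by 0.51 ± 0.0599, and Meis2 rose by 0.30 ± 0.0566. Hoxd12 fell by 1.91 ± 0.108, Cyp26b1, a retinoic acid degrading enzyme, by 1.26 ± 0.0953, Lhx2 by 1.17 ± 0.0973 and Lhx9 by 1.14 ± 0.136. BMP and TGF-beta targets fell with Msx2, Bmp4 and Id1 lower of 16 (8 lower and 1 higher adjusted over the list alone), at a median of -0.21 (adjusted p = 8.3e-06; adjusted p = 0.418 with an estimated correlation). Wnt targets had a median of -0.18 with none of 13 past singly (4 lower adjusted over the list alone; adjusted p = 2.13e-06; adjusted p = 0.422 with an estimated correlation). Mesenchyme genes had a median of -0.16 with Prrx1 lower (6 adjusted over the list alone; adjusted p = 7.28e-07; adjusted p = 0.699 with an estimated correlation). Cartilage genes had a median of -0.0818 with Col9a3 lower (4 lower and 1 higher adjusted over the list alone; adjusted p = 0.00615; adjusted p = 0.699 with an estimated correlation), and of -0.0856 without tph2+/- replicate 2 (adjusted p = 0.0521). Megakaryocyte genes had a median of -0.26, none past singly (5 lower adjusted over the list alone; adjusted p = 1.99e-05; adjusted p = 0.396 with an estimated correlation). Cardiac muscle genes had a median of -0.51 (1 lower over all genes, Tbx5, and 2 adjusted over the list alone; adjusted p = 0.000884; adjusted p = 0.772 with an estimated correlation). That list rested on tph2+/- replicate 2, without which its median was 0.0348 (adjusted p = 0.643). Hepatoblast genes had a median of 0.22, none past singly, also when adjusted over the list alone (adjusted p = 0.000716; adjusted p = 0.772 with an estimated correlation). That median was -0.0286 without tph2+/- replicate 1 (adjusted p = 0.62) and -0.0387 with Y-linked expression in the fit (adjusted p = 0.423). The haematopoietic stem and progenitor list did not pass (median 0.0525, adjusted p = 0.452), and Kit had 0.11 ± 0.0638 (adjusted p = 0.503).

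The trend over the number of intact alleles fits 1 straight line and asks whether expression followed dose. No step is tested by itself, so a gene that moved in 1 step can pass. Male libraries became more frequent as alleles were lost, so the slope follows sex as well. Of 8 tested neural tube and neuron genes 3 passed with a rising slope, Sox2 at 0.85 ± 0.0733 log2 units per lost allele (adjusted p = 0.0045), Map2 at 0.57 ± 0.039 (adjusted p = 0.0013) and Dcx at 0.63 ± 0.0475 (adjusted p = 0.00189). Fabp7 (adjusted p = 0.0714), Elavl3 (0.0806), Nkx6-1 (0.108), Nefm (0.225) and Nefl (0.333) did not pass, and Nefl stood at 23.3, 18.6 and 37.7 RPKM in tph2+/+, tph2+/- and tph2-/-. Kit had a slope of 0.19 ± 0.0346 per lost allele (adjusted p = 0.0353), though it did not pass between tph2+/- and tph2-/- (limma adjusted p = 0.503). The slope was -0.37 ± 0.0433 for Tbx3 (adjusted p = 0.0207) and -0.30 ± 0.0404 for Bmp4 (adjusted p = 0.0215). Of 12869 genes 291 passed by limma, 169 with a rising and 122 with a falling slope over lost alleles. After quantile normalization 146 rose and 205 fell. Alb (adjusted p = 0.122) and Barx1 (adjusted p = 0.161) did not pass; Barx1 stood at 26.0 RPKM in tph2+/- and 23.6 in tph2-/-. The count rested on single libraries. It was 6 and 5 without tph2+/+ replicate 1 or 2, 3 and 5 without tph2-/- replicate 1 or 2, 778 without tph2+/- replicate 2, and 8 with Y-linked expression in the fit, of which Acta2, Tnc and Fam181b, the last named after its value was seen, were among the 291. With that term Sox2 had 0.80 ± 0.137 (adjusted p = 0.14), Map2 0.57 ± 0.072 (0.0583), Dcx 0.67 ± 0.0864 (0.0583), Kit 0.18 ± 0.0642 (0.407), Tbx3 -0.37 ± 0.0825 (0.204) and Bmp4 -0.275 ± 0.0755 (0.299), with larger errors than without it.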

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

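The tests of sex, liver tissue, shared transcripts and blood cells in this part, except the slope over autosomal genes, were chosen after the results they measure had been seen, while the list tests of tph2-/- against tph2+/- were planned, and the counts with Y-linked expression in the fit were known when that slope was set.

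Liver genes were higher in both mutant genotypes, with medians over 17 hepatoblast genes of 2.59 in tph2-/- and 2.28 in tph2+/- against tph2+/+. Sex as the whole source is argued against, since with Y-linked expression as a term in the fit the tph2-/- median was 2 (95% bootstrap interval 1.44 to 2.42), with 17 of 17 genes past the threshold, and in the female tph2+/- replicate 1 alone the median over tph2+/+ was 1.98 (quartiles 1.56 to 2.33); the term rests on 1 male and 1 female tph2+/- library, and the interval covers genes only. Liver tissue taken with the dissected piece may account for the rise. A single amount of tissue per library would lift all liver genes by 1 factor. The excess in tph2+/- replicate 1 was a median 0.623 of that in tph2-/- replicate 1, with an SD of the log2 share of 0.225. Shares were not equal, from 0.431 for Apob to 0.792 for Ttr, and the limit on the SD was set after the values were seen. The check therefore cannot single out liver tissue. A larger liver in mutant embryos would give the same proportions, so the genotype stays open and was not tested apart from dissection. Genes of other tissues also differed from near 0. Barx1 stood at 0.463 RPKM in tph2+/+, 26.05 in tph2+/- and 23.57 in tph2-/-, and Pdx1 at 0, 59 and 66 reads. The cardiac list mean was 3.503 in tph2+/- replicate 2 and at most 2.367 in any other library. Whether the dissected pieces differed in tissue beyond liver was not tested.

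The count of genes past the threshold in tph2-/- against tph2+/+, 1241, coincides with a difference of sex. If sex set the autosomal part, the male minus female difference within tph2+/- should follow it with a slope near 1. Over 1209 autosomal genes the slope was 0.12 (bootstrap interval 0.0954 to 0.142). The slope weights each gene by its squared fold change, and the genes were chosen by that same difference. It argues against sex as the main source of the larger autosomal changes. It does not say how many of the calls came from sex. Also, tph2+/- held 1 library of each sex, the interval covers genes and not libraries, and a smaller contribution could remain. The 422 genes past the threshold with Y-linked expression in the fit, of which 285 were among the 1241, come from a fit with less information on genotype.

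Genes of haematopoietic stem and progenitor cells were higher in both mutant genotypes, with medians of 0.41 and 0.26 over 23 genes. Sex cannot be told apart from genotype here: with Y-linked expression in the fit the median was 0.262 (bootstrap interval over genes 0.0648 to 0.627, 9 of 23 genes higher) and the list passed (adjusted p = 3.08e-05), but that term rests on 1 male and 1 female tph2+/- library. The female one had a list mean of 2.822 against 2.434 and 2.454 in tph2+/+ and 2.869 to 2.89 in the male libraries, and its differences from tph2+/+ had quartiles over genes of -0.00948 to 0.745. Transcripts shared with megakaryocytes and erythroid cells cannot be told apart from progenitors: the 15 members not shared had a median of 0.0823 (quartiles 0.0214 to 0.62), yet 6 of them rose. Blood cells brought along with liver tissue cannot be told apart from more progenitors in mutant embryos. Here the excess in tph2+/- replicate 1 was divided by the mean excess of the other mutant libraries. The median share was 0.771 for 13 of these genes and 0.622 for hepatoblast genes. The 13 genes were those past the threshold in either mutant genotype and higher in tph2-/-, so the measured libraries also chose them. With overlapping quartiles (0.622 to 0.813 and 0.59 to 0.672) that difference of 0.149 decides neither way.

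The effects of the 2 mutant genotypes against tph2+/+ differed for 10 gene lists, by the camera test of tph2-/- against tph2+/-. None of these calls held with an estimated correlation, where the test rests on 3 residual degrees of freedom. The median log2 difference was 0.903 for neural tube and neuron genes, 0.191 for sympathoadrenal and neural crest genes and 0.218 for hepatoblast genes. It was -0.264 for limb bud genes, -0.255 for megakaryocyte and platelet genes, -0.21 for BMP and TGF-beta targets, -0.18 for Wnt targets and -0.161 for mesenchyme and extracellular matrix genes. It was -0.0818 for cartilage genes and -0.507 for cardiac muscle genes. Without tph2+/- replicate 1 the hepatoblast median was -0.0286, and without tph2+/- replicate 2 the cardiac median was 0.0348 and the cartilage median -0.0856 (adjusted p = 0.0521).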

How the results depend on the processing

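Tests with the clone rows and without X and Y genes were chosen after the data had been seen, and the cause of the changes below was not tested unless stated. In order tph2-/- against tph2+/+, tph2+/- against tph2+/+, tph2-/- against tph2+/- and trend, the reported 1241, 782, 166 and 291 genes ranged from 383 to 1530, 325 to 805, 57 to 288 and 3 to 778 when each library was left out; a lone library was assumed to vary like the other groups. A mean of at least 5 RPKM, which tests fewer genes, gave 795, 439 and 91; an adjusted p under 0.10 gave 2107, 1269, 288 and 993; an unadjusted p under 0.05 with a 2-fold change gave 121, 111, 43 and 32. Y-linked expression as a covariate gave 422, 269 for tph2-/- against tph2+/- and 8 for the trend, and no filter gave 41 for the trend. With the replicate number as a block the counts were 1649, 908, 220 and 161; deviations of libraries with the same number correlated at 0.033, 0.17 and 0.0727, and the labels speak of littermates without tying these numbers to litters, so pairing stays unknown. The clone rows gave 1227, 808, 166 and 277, and leaving out X and Y genes 1222, 773, 166 and 300. Of gene lists, 0, 0 and 0 passed with an estimated correlation and 7, 7 and 2 by fry. Named genes kept their call in every fit that left out a library for 48 of 92, 58 of 95 and 24 of 34, and lists for 20 of 21, 12 of 25 and 7 of 10; most gene calls were lost without tph2-/- replicate 1 (41 of 92) and tph2+/+ replicate 2 (38 and 34). With Y-linked expression as a covariate 50, 79 and 31 gene calls and 14, 19 and 9 list calls were kept. In tph2-/- against tph2+/- that covariate turned the medians of the erythroid (-0.196) and hepatoblast (-0.0387) lists. Left-out libraries gave ranges of -0.184 to 0.216 for erythroid, -0.0286 to 0.464 for hepatoblast and -0.269 to 0.125 for somite genes, and of -0.229 to -0.0032 for mesenchyme genes in tph2+/- against tph2+/+. Myl4 in tph2+/- against tph2+/+ had -0.5057 with the covariate, 0.5476 without tph2+/- replicate 1 and -0.4997 without tph2+/- replicate 2. Only tph2+/- replicate 2 was high in cardiac genes, which goes with the first of these left-out values and leaves the fall in the second unexplained. Alternatives that need counts (other scaling factors, count tests and library sizes without erythroid or mitochondrial genes) were not run on RPKM values. Depth limited Tph2, Tph1 and Fasl, with at most 17 reads in a library.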

Other observations

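Genes outside the fixed lists were looked at after their values were seen. The metallothionein genes Mt1 and Mt2, which encode metal-binding proteins and have close paralogs, rose in both mutant genotypes. Mt1 was at 49.7 and 49.5 RPKM in tph2+/+, 96.1 and 100.5 in tph2+/- and 131.5 and 137.9 in tph2-/- (log2 fold change of tph2-/- 1.42 ± 0.053 SE, limma adjusted p = 2.86e-06), and it was also higher in tph2-/- than in tph2+/- (0.45 ± 0.053, adjusted p = 0.00353). Gcg, the glucagon gene, was at 0.0199 and 0 RPKM in tph2+/+, 3.93 and 4.06 in tph2+/- and 3.05 and 4.25 in tph2-/- (adjusted p = 2.74e-05 in tph2-/-). Foxf1, a factor of gut and lung mesenchyme, was at 5.19 and 5.85 RPKM in tph2+/+ and 13.7 and 16.3 in tph2-/- (1.29 ± 0.0876, adjusted p = 6.49e-05), and Fendrr, annotated beside it, had 1.48 ± 0.0898, though strand was not marked. Fermt3, an integrin activator of blood cells, rose by 1.16 ± 0.0695 and Mpo, the myeloperoxidase gene, by 1.59 ± 0.114 in tph2-/-. Hoxc6 fell by 0.61 ± 0.0585 in tph2-/- and Hoxc8 fell by 0.55 ± 0.0656.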
